A study of Arabidopsis thaliana with 12 samples.

How the data were processed

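Inflorescence meristems of Col-0 and pRPS5A::GR-bdl plants were treated for 2 h with dex or with solvent, dissected and frozen, 5 inflorescences per sample, per the labels' protocols. RNA was read in pairs on an Illumina HiSeq instrument, and adaptors, low-quality reads and ribosomal reads were removed, per the labels' protocols. The deposited files hold raw read counts per locus, which the authors made with TopHat2 2.0.14 and HTSeq 0.9.1 on TAIR10, per the submitters' processing notes. That the values are unnormalized counts was checked on the files, which hold whole numbers for 32678 loci with a different total in each sample. The annotation release, the strand of counting and the handling of reads with several alignments are not stated. Gene names, overlaps and neighbours were taken from a table of the TAIR10.1 assembly, in which 31912 of the loci were found and 766 were not, and no coordinates of it are given.

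All 12 samples entered one model of 4 group means in edgeR 4.0.16 (R 4.3.3), with TMM normalization and the filter filterByExpr by group, which kept 19384 loci. Each of 5 comparisons was tested with the two-sided quasi-likelihood F test, namely dex against mock in GR-bdl, dex against mock in Col-0, the difference of these responses, and GR-bdl against Col-0 in mock and in dex. A locus passed at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the root of F. Levels are CPM with TMM factors, and the prior count on the log scale was 2. Totals were 26352517 to 34245036 counts per sample, the 10 most abundant loci took 2.36 to 3.02% of them, and organelle loci took 0.011 to 0.033%. The common dispersion corresponds to a coefficient of variation of 0.201. Replicates of a group differed by a chi-square per gene of 16.6 to 101.66, where counting alone gives 1. On average over genes the spread between samples thus exceeded counting error, an average in which abundant loci weigh most. Counting intervals are exact at 95%, the floor for a count of 0 is 3 counts over a group, and both cover counting error only. The median log2 fold change over all loci lay within 0.007 of 0 in every comparison.

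Before the data were examined 22 gene lists with 392 genes were fixed, covering auxin response, transport and synthesis, MP-dependent genes, cytokinin, gibberellin, meristem, boundary, floral and polarity genes, cell division, cell walls, the clock, wounding and markers of other tissues. IAA12 was kept out of the Aux/IAA list because the transgene carries its sequence, 1 member was left out for want of a matching name, and 3 members had no symbol in the reference. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 22 lists, and again with an estimated correlation and with fry. The list tests of the genotype comparisons were added after the data were seen. The genes named in the text also follow a rule fixed beforehand. In GR-bdl dex against mock and in the difference of responses these are up to 10 loci in each direction with the largest change among those past the threshold with a mean of at least 1 CPM, and in a direct comparison with no overlap between the groups. In the other comparisons they are up to 5 in each direction. To these come up to 4 members of each list past the threshold over all genes, and IAA12 and the qPCR genes AHP6, PIN1, ARF5, PID and AT1G04850 whatever their values. Other list members are given only with their values.

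The labels describe a harvest in numbered rounds, each with 1 sample of every group and mock before dex, and the sample titles carry replicate numbers 1 to 3 for Col-0 and 2 to 4 for GR-bdl. No label states outright that the title numbers are those rounds. They were taken as pairs on that ground, and a model with the replicate number as a block was an alternative, with 5 residual degrees of freedom where the unblocked model has 8. Deviations from the group means of samples with the same number correlated at −0.169 to 0.326 within genotypes, over 0.1 in 2 of 6 pairs, and at −0.277 to 0.368 over all 14 pairs, of which 5 were over 0.1. Those 2 within genotypes were Col-0 pairs (0.154 and 0.326), and the GR-bdl pairs stood at −0.169, −0.141 and −0.049.

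Other alternatives fixed beforehand were RLE size factors, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, a model of the compared groups alone, adjusted p under 0.01, a test against a fold of 1.2 and leaving out each sample in turn. Library quality weights, and leaving out the 2 samples with the lowest weights, were added after the data were seen. The IAA12 level was compared between 6 and 6 samples with an exact permutation test. The workflow was tested on simulated data with 200 changed genes among 19264. For dex against mock in GR-bdl it recovered 6% of changes of 0.5 on the log2 scale, 80% of changes of 1, 94% of changes of 2 and 96% of changes of 3, with 6 false calls among 144. For the difference of responses the shares were 0%, 40%, 90% and 96%, with 2 false calls among 115. The changed genes were drawn from better expressed loci outside the gene lists, and each gene had the same spread in every sample. The shares therefore do not carry over to weakly expressed loci or to samples of unequal spread. A list shifted by −0.5 was found and 0 other lists were called, in simulated genes without correlation.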

Results

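RNA sequencing counts were obtained from dissected inflorescence meristems of Arabidopsis thaliana, the shoot tips on which flowers form. Col-0, the wild type, was set beside pRPS5A::GR-bdl (GR-bdl), a line that expresses bdl in dividing tissue. The bdl allele encodes a stabilized form of IAA12 (BODENLOS), an Aux/IAA protein that binds the auxin response factor ARF5 (MONOPTEROS, MP) and represses its targets. Its fusion to the glucocorticoid receptor (GR) is held outside the nucleus until dexamethasone (dex) is supplied. Plants of each genotype were treated for 2 h with dex or with solvent alone (mock). The dose is 50 µM in the treatment protocol and 10 µM in the design text of the series, so it is left open here. There were 4 groups of 3 samples, each a pool of 5 inflorescences. Counts totalled 26352517 to 34245036 per sample, and 21322 to 21996 of the 32678 listed loci had a read.

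The line itself was recognisable from IAA12 (AT1G04550), the locus whose coding sequence the transgene carries. Its level was 251 ± 13.9 CPM (counts scaled to library size; SD, n = 6) in the GR-bdl samples and 45.6 ± 4.03 (SD, n = 6) in the Col-0 samples, a ratio of 5.50. The lowest GR-bdl sample, at 238 CPM, lay far above the highest Col-0 sample, at 49.8 CPM. A two-sided exact permutation test over the 924 splits of the samples gave p = 0.0021645, the smallest it can give. In GR-bdl dex against mock its log2 fold change was −0.08 (SE 0.10), which did not pass the test.

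**Figure D1:**
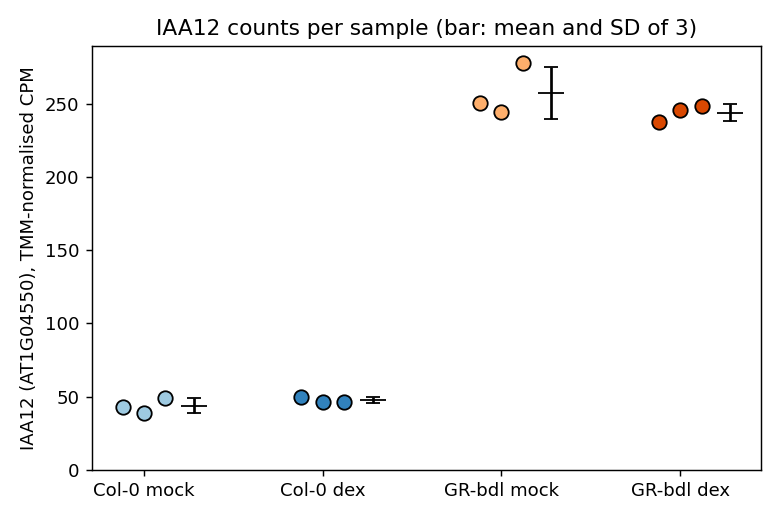
IAA12 level in CPM (vertical axis) for each of the 12 samples, by group, with the group mean and SD. All GR-bdl samples lie at or above 238 CPM and all Col-0 samples at or below 49.8 CPM.

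The first question was which transcripts change within 2 h of dex in the GR-bdl meristem. In all 10 loci passed the test over all genes, and each of them fell. GH3.2 (AT4G37390) and GH3.3 (AT2G23170), enzymes that conjugate auxin to amino acids, fell by 1.90 (SE 0.21, adjusted p = 0.013) and by 1.46 (SE 0.21, adjusted p = 0.0372) on the log2 scale. MAKR6 (AT5G52900), of the family of membrane-associated kinase regulators, fell by 2.55 (SE 0.31, adjusted p = 0.0197), from 7.77 ± 1.11 to 1.32 ± 0.213 CPM (SD, 3 samples each). AHP6 (AT1G80100), an inhibitor of cytokinin signalling that marks early flower primordia, fell by 1.41 (SE 0.21, adjusted p = 0.0431), from 22.1 ± 4.21 to 8.31 ± 1.59 CPM. NPY5 (AT4G37590), which acts with protein kinases in organ initiation, fell by 1.05 (SE 0.12, adjusted p = 0.013). The auxin-inducible HD-ZIP II transcription factor HAT2 (AT5G47370) fell by 1.39 (SE 0.20, adjusted p = 0.0372), and the Dof transcription factor OBP1 (AT3G50410) by 0.79 (SE 0.11, adjusted p = 0.0372). The rest were AT1G21050 (−1.40, SE 0.19), AT1G66940 (−1.07, SE 0.14) and AT1G67900 (−0.65, SE 0.084), with adjusted p of 0.0257 to 0.0372. AT1G66940 overlaps AT1G66930 and the strand of counting is not stated, so its value is uncertain.

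The log2 fold changes of these 10 loci in Col-0 ran from −0.32 to 0.28, and none passed the test there. All of them had their highest group mean in GR-bdl mock. NPY5 stood at 103 ± 13.7 CPM in Col-0 mock, 119 ± 9.77 in Col-0 dex, 159 ± 12.3 in GR-bdl mock and 76.8 ± 3.94 in GR-bdl dex (SD, 3 samples each). An unadjusted p under 0.05 was found for 1505 loci, where 969 would by chance, and of these 895 were higher and 610 lower. With the replicate number as a block 0 of the 10 passed, at adjusted p of 0.0911 to 0.209, while their log2 fold changes moved by at most 0.025. The count was 5 without GR-bdl dex 3, 1 without GR-bdl mock 3 and 0 without any other of the 6 samples, and it was 65 with DESeq2, 1706 with library quality weights and 3336 without the 2 samples of lowest weight. Of those 2, Col-0 mock 2 and GR-bdl dex 4, only GR-bdl dex 4 enters this comparison, and without it alone the count was 0. In both runs the log2 fold changes of the 10 loci moved by at most 0.206. The step from 0 to 3336 thus came with also removing a Col-0 sample that only shares the fit. The count without that Col-0 sample alone is not given here, so the part of each sample is not told apart.

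**Figure D2:**
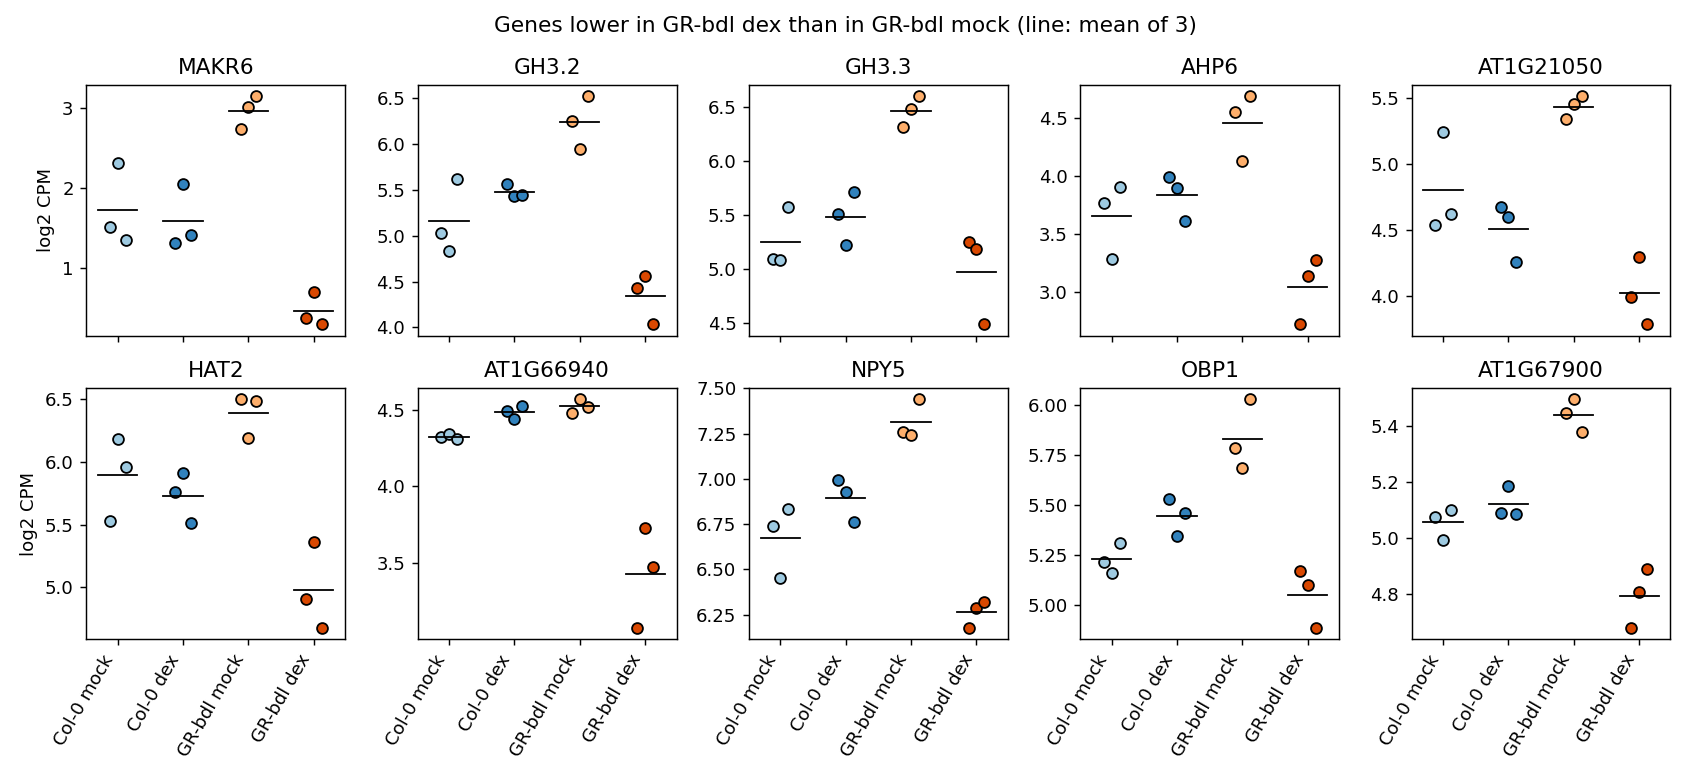
Levels in CPM (log axis) of the 10 loci that fell in GR-bdl after dex, for each of the 12 samples, with group means. In every panel the GR-bdl dex samples lie below the GR-bdl mock samples.

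Most tested members of the auxin-response families had lower levels in GR-bdl after dex, few of them past the test as single genes. Of 24 Aux/IAA genes tested, the early auxin-induced repressors other than IAA12, 23 had a log2 fold change below 0, with a median of −0.54 (adjusted p = 1.99e-16, camera). IAA1 had −2.12 (SE 0.37), IAA2 −1.79 (SE 0.34) and IAA30 −1.76 (SE 0.27). Adjusted over the list alone 12 Aux/IAA genes fell, against 0 over all genes. All 6 GH3 genes tested lay below 0 (median −0.50, adjusted p = 6.76e-15), and 3 fell when adjusted over the list alone against 2 over all genes. Among auxin carriers and the proteins that set their polarity 19 of 24 lay below 0 (median −0.23, adjusted p = 1.06e-05). PIN3 (−0.90, SE 0.16) and PIN6 (−0.64, SE 0.15) were among the 3 that fell adjusted over the list alone. These 3 lists were also lower with an estimated correlation between genes, at adjusted p of 0.00504, 0.000741 and 0.0284. SAUR genes, small auxin-induced transcripts, had 19 of 21 members below 0 and a median of −0.54 (adjusted p = 2.62e-06), with SAUR14 at −1.17 (SE 0.47) and SAUR50 at −0.39 (SE 0.14). None of the SAUR genes passed alone, and the adjusted p was 0.0596 with an estimated correlation. Without GR-bdl dex 4 the medians were −0.84 for SAUR and −0.36 for auxin transport genes, and without GR-bdl mock 2 the SAUR median was −0.34. Markers of vascular tissue moved with all of these lists, 9 of 9 lying lower after dex at a median of −0.74 (adjusted p = 2.62e-06, and 0.107 with an estimated correlation). Auxin response factors (median 0.07) and auxin biosynthesis genes (median 0.23) did not pass as lists. Adjusted over the list alone, YUC1 (0.39, SE 0.11) and YUC4 (0.44, SE 0.16) were higher and TAA1 (−0.54, SE 0.20) lower.

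The lists of cytokinin genes and of MP-dependent genes passed in the downward direction with the preset correlation and not with an estimated one, in the same samples in which the vascular markers were lower. The cytokinin list, which holds response regulators, metabolic enzymes and AHP6, had 18 of 22 members below 0 (median −0.43, adjusted p = 1.28e-09, and 0.0596 with an estimated correlation). The cytokinin oxidases CKX6 (−1.40, SE 0.26) and CKX5 (−0.95, SE 0.19) and the response regulators ARR15 (−0.97, SE 0.31) and ARR4 (−0.56, SE 0.17) fell when adjusted over the list alone, 6 members in all against 1 over all genes. In the list of MP-dependent primordium genes 12 of 19 lay below 0 (median −0.29, adjusted p = 1.42e-06, and 0.154 with an estimated correlation). Adjusted over that list alone 7 fell against 1 over all genes, among them DOF5.8 (−1.40, SE 0.22), DRNL (−1.33, SE 0.23), a regulator of organ founder cells, and TMO5 (−1.21, SE 0.28). AHP6 belongs to both lists and is the 1 locus past the test over all genes in each. Other members stood above 0, such as FIL (0.86, SE 0.35). The call for this list was lost without GR-bdl dex 4 (adjusted p = 0.118, median −0.12), and its median was −0.46 without GR-bdl dex 3.

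Organ boundary genes were higher after dex in GR-bdl, 9 of 11 lying above 0 at a median of 0.38 (adjusted p = 0.000714, and 0.244 with an estimated correlation). BOP2 (0.65, SE 0.15) and LAS (0.44, SE 0.12), which act at the base of lateral organs and in their axils, rose when adjusted over the list alone, against 0 members over all genes. The boundary median was 0.22 without GR-bdl dex 3 and 0.23 without GR-bdl mock 4. Floral identity regulators had 14 of 22 members above 0 (median 0.28, adjusted p = 0.00736, and 0.172 with an estimated correlation), including AP3 (0.51, SE 0.20) and AG (0.52, SE 0.22), and the call was lost without GR-bdl dex 3 (adjusted p = 0.0687, median 0.125). Both lists moved against the fall in vascular markers. Epidermal markers (median 0.28, adjusted p = 0.0201) and circadian clock genes (median 0.20, adjusted p = 0.0113) also passed, with adjusted p of 0.432 and 0.0853 under an estimated correlation. The epidermal median was 0.18 without GR-bdl dex 3 and 0.51 without GR-bdl mock 3. The epidermal call was lost without GR-bdl dex 3 (0.144) and without GR-bdl mock 4 (0.0827), and the clock call without GR-bdl dex 4 (0.11). Gibberellin metabolism passed in the downward direction (median −0.08, mean −0.53, adjusted p = 0.0252, and 0.107 with an estimated correlation). Its GA2OX1, a gibberellin-inactivating oxidase, stood at 0.449 ± 0.0784 CPM in mock and 0.0333 ± 0.00185 in dex, and the call was lost without GR-bdl dex 3 (0.0734), GR-bdl dex 4 (0.152) or GR-bdl mock 3 (0.0694) and with loci under a mean of 1 CPM removed (0.451). Leaving out any GR-bdl sample but GR-bdl mock 3 moved the gibberellin median by over 1.5 times, from −0.66 without GR-bdl dex 2 to 0.005 without GR-bdl mock 4. Lists for meristem maintenance (median 0.17), organ polarity (0.22), mitosis (0.06), DNA replication (0.13), cell wall loosening (−0.08), wounding (0.32), the tapetum (0.16) and photosynthetic tissue (−0.06) did not pass. In all 12 of 22 lists passed with the preset correlation, where other splits of the 6 samples gave up to 10, and 3 passed with an estimated correlation, where other splits gave 0.

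**Figure D3:**
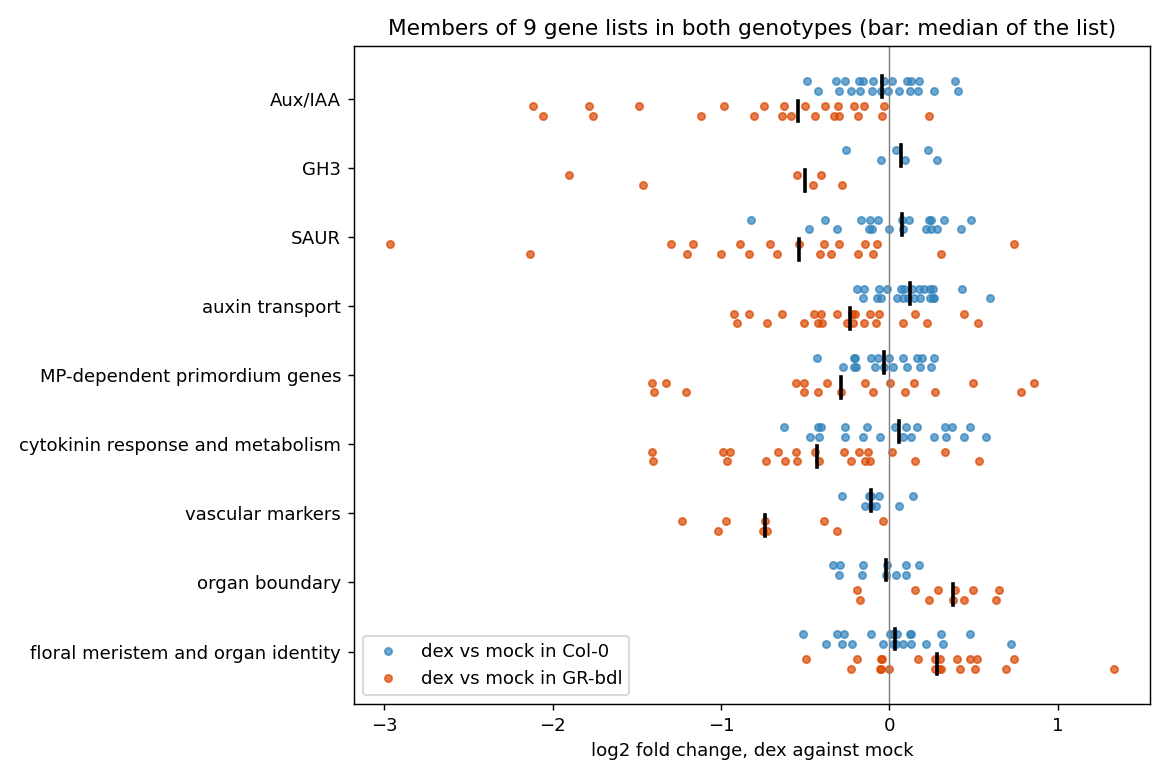
Log2 fold change of dex against mock (horizontal axis) for each tested member of 9 gene lists, in Col-0 and in GR-bdl, with the median of each list as a bar. In GR-bdl the Aux/IAA, GH3 and SAUR medians are −0.54, −0.50 and −0.54, and in Col-0 they are −0.04, 0.07 and 0.07.

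Among the genes that the labels name as checked by qPCR, AHP6 alone passed in GR-bdl. PIN1 (AT1G73590), the main auxin efflux carrier of the shoot tip, had a log2 fold change of −0.51 (SE 0.13, adjusted p = 0.572). PID (AT2G34650), the kinase that directs PIN1, had −0.42 (SE 0.18, adjusted p = 0.572). ARF5 (AT1G19850) itself had 0.07 (SE 0.12) and the reference gene AT1G04850 had 0.13 (SE 0.10). ARF5 overlaps AT1G19860, which leaves its value uncertain.

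The Col-0 comparison asked what dex does without the fusion protein. No locus passed the test in edgeR, DESeq2 or limma-voom, and 673 had an unadjusted p under 0.05 where 969 would by chance. PIN1 had a log2 fold change of 0.18 (SE 0.13) and AHP6 had 0.17 (SE 0.20). The auxin families were near 0, with medians of −0.04 for Aux/IAA, 0.07 for GH3 and 0.07 for SAUR, and vascular markers had −0.11. Cell division genes passed as lists with small shifts. DNA replication genes had 11 of 11 members above 0 (median 0.25, adjusted p = 5.07e-05), with MCM6 at 0.38 (SE 0.13) and CDC6 at 0.44 (SE 0.18). Mitotic genes had 19 of 21 above 0 (median 0.10, adjusted p = 5.07e-05), with CDKB1;2 at 0.37 (SE 0.14). Wound, touch and jasmonate genes had 25 of 35 below 0 (median −0.43, adjusted p = 0.0119), with JAZ8 at −2.78 (SE 1.09). Epidermal markers (median 0.25, adjusted p = 0.0237) and auxin transport genes (median 0.13, adjusted p = 0.0291) passed in the upward direction. None of these 5 lists passed with an estimated correlation, at adjusted p of 0.619 for DNA replication, 0.377 for mitosis, 0.905 for wounding, 0.873 for the epidermis and 0.377 for auxin transport. Other splits of the Col-0 samples gave up to 11 lists. The DNA replication call was lost without Col-0 dex 1 (0.278), the wounding call without Col-0 dex 1, mock 1 or mock 2, the epidermal call without Col-0 dex 1, dex 3, mock 1 or mock 2 or with loci under a mean of 1 CPM removed (0.103), and the auxin transport call without any sample but Col-0 dex 2. Without Col-0 dex 1 the medians were 0.08 for DNA replication and −0.18 for wounding, without Col-0 dex 2 they were 0.41 for DNA replication, 0.18 for mitosis and 0.41 for the epidermis, and without Col-0 dex 3 they were −0.655 for wounding and 0.13 for the epidermis. Without Col-0 mock 2 they were −0.13 for wounding and 0.08 for auxin transport, and without Col-0 mock 3 they were 0.39 for DNA replication and 0.37 for the epidermis.

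Whether the response to dex differed between the genotypes was tested as the difference of the log2 fold changes, GR-bdl minus Col-0. The auxin families differed as lists. The median difference was −0.68 for Aux/IAA (adjusted p = 1.77e-07), −0.47 for GH3 (adjusted p = 2.47e-08) and −0.44 for auxin transport (adjusted p = 2.47e-05), and with an estimated correlation the adjusted p were 0.0437, 0.00544 and 0.0404. SAUR genes had −0.84 (adjusted p = 0.000664, and 0.148 with an estimated correlation) and cytokinin genes −0.50 (adjusted p = 0.000251, and 0.25). Vascular markers differed in the same direction, by a median of −0.65 (adjusted p = 0.0112, and 0.429 with an estimated correlation). The call for vascular markers was lost without Col-0 dex 2 or Col-0 mock 3 and with loci under a mean of 1 CPM removed (0.0761). The vascular median was −0.39 without Col-0 dex 2, and the SAUR median was −0.50 without Col-0 dex 1 and −0.55 without GR-bdl mock 2. Among single genes the differences were −2.39 for MAKR6, −2.19 for GH3.2, −1.69 for GH3.3, −1.58 for AHP6 and −1.26 for NPY5. No locus passed the test of the difference in edgeR, where the smallest adjusted p was 0.0848 and 2008 loci had an unadjusted p under 0.05. limma-voom gave 0 as well and DESeq2 gave 31. In all 11 lists passed with the preset correlation and 3 with an estimated one, and other splits within the genotypes gave up to 14 and 8. Mitotic genes did not pass in the test on all samples (adjusted p = 0.0922, median −0.06) and did in some other settings, the replicate block among them (adjusted p = 0.048, median −0.05).

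The line was also compared with Col-0 without dex, to see what it carries before induction. GH3 genes were higher in GR-bdl mock, 6 of 6 lying above 0 at a median of 0.56 (adjusted p = 2.35e-07, and 0.00829 with an estimated correlation). Adjusted over the list alone GH3.3 (1.21), GH3.2 (1.06), GH3.6 (0.59) and GH3.9 (0.53) were higher, against 0 over all genes. Vascular markers lay higher beside them, 9 of 9 at a median of 0.65 (adjusted p = 0.00749, 0.492 with an estimated correlation and 0.0594 with the replicate block), a call lost without Col-0 mock 3 (0.0972). Wound, touch and jasmonate genes were lower (median −0.52, adjusted p = 0.0023, and 0.588 with an estimated correlation), a call lost without Col-0 mock 2 (0.194, median −0.33) or GR-bdl mock 2 (0.0595). Without Col-0 mock 3 the wounding median was −0.82. Auxin transport genes were higher (median 0.20, adjusted p = 0.0178, and 0.248 with an estimated correlation), a call lost without Col-0 mock 2 (0.118, median 0.13). With the replicate block mitotic genes (median 0.08, adjusted p = 0.00797) and clock genes (median −0.19, adjusted p = 0.00804) passed as well. Neither did in the test on all samples without it, though clock genes also did in some other settings.

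Over all genes 11 loci were higher and 8 lower in GR-bdl mock. IAA12 was higher by 2.56 (SE 0.11, adjusted p = 2.81e-07), cycp3;1 (AT2G45080), a P-type cyclin, by 1.94 (SE 0.20, adjusted p = 0.00145) and XTH15 (AT4G14130), a xyloglucan endotransglucosylase, by 1.93 (SE 0.17, adjusted p = 0.000644). XTH15 overlaps AT4G14120, which leaves its value uncertain. AT4G22390 (1.38, SE 0.18) and AT1G33790 (1.23, SE 0.19) were higher too. A few loci had almost no reads in the line. AT4G03923, listed as a pseudogene, had 0 counts in the 3 GR-bdl mock samples and 2172 in the 3 Col-0 mock samples, at least 705-fold lower against a floor of 3 counts per group. MRD1 (AT1G53480) had 2 against 5834 counts, a ratio of 2839 (95% counting interval 785 to 23446). AT1G53887 had 2 against 421 counts, a ratio of 205 (56.4 to 1697). HEI10 (AT1G53490), which acts in meiotic crossover formation, had −1.91 (SE 0.15, adjusted p = 0.000195) and CYP72A13 (AT3G14660) had −1.70 (SE 0.15, adjusted p = 0.000644). HEI10 and MRD1 overlap each other and AT1G07887, and HEI10 also overlaps AT1G53500, so both values are uncertain. With the replicate block 7 loci passed, 3 higher and 4 lower, and the count was 12 without Col-0 mock 1, 11 without Col-0 mock 2, 11 without GR-bdl mock 3 and 9 without GR-bdl mock 4.

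After dex the lowest adjusted p of a list between the genotypes was that of the Aux/IAA genes, 20 of 24 lying lower in GR-bdl dex than in Col-0 dex at a median of −0.41 (adjusted p = 8.73e-06, and 0.214 with an estimated correlation). Vascular markers did not pass here (median −0.02), nor did GH3 genes (median −0.07, mean −0.24, adjusted p = 0.0698). MP-dependent genes (median −0.30, adjusted p = 0.000146, and 0.415 with an estimated correlation), auxin transport genes (median −0.27, adjusted p = 0.00862, and 0.311), cytokinin genes (median −0.20, adjusted p = 0.00862, and 0.433) and SAUR genes (median −0.47, adjusted p = 0.029, and 0.415) were also lower. Photosynthetic tissue markers were lower in the same samples, 9 of 9 at a median of −0.65 (adjusted p = 0.00862, and 0.415 with an estimated correlation). Organ boundary genes passed in the upward direction with the replicate block (adjusted p = 0.00373, median 0.25) and some other settings, and not in the test on all samples. Without Col-0 dex 3 the calls for auxin transport, SAUR and photosynthetic genes were lost, without GR-bdl dex 4 those for MP-dependent, auxin transport and cytokinin genes, without Col-0 dex 2 that for cytokinin genes, and without GR-bdl dex 2 that for SAUR genes, which was also lost with loci under a mean of 1 CPM removed (0.31). The Aux/IAA median was −0.27 and the photosynthetic median −0.355 without Col-0 dex 3, the MP-dependent median −0.16 without GR-bdl dex 4, and the auxin transport median −0.18 without GR-bdl dex 3. The cytokinin median was −0.32 without Col-0 dex 1, −0.11 without Col-0 dex 2 and −0.34 without GR-bdl dex 3. The SAUR median was −0.24 without Col-0 dex 2, −0.235 without Col-0 dex 3, −0.22 without GR-bdl dex 2 and −0.29 without GR-bdl dex 3.

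Over all genes 25 loci were higher and 27 lower in GR-bdl dex. Cell wall genes stood on both sides. XTH15 was higher by 2.37 (SE 0.18, adjusted p = 0.000115) and XTH16 (AT3G23730) by 1.68 (SE 0.30, adjusted p = 0.0444), while the expansin EXPB1 (AT2G20750) had −1.35 (adjusted p = 0.0233). FLA13 (AT5G44130), an arabinogalactan protein, was higher by 1.71 (SE 0.24) and AT2G23690 by 1.53 (SE 0.22). The sucrose transporter SUC1 (AT1G71880) had −1.56 (SE 0.23, adjusted p = 0.0159). DOF5.8 (AT5G66940), a target of MP, had −1.35 (adjusted p = 0.0361). GA2OX1 (AT1G78440) had 3 against 47 counts, a ratio of 15.6 (95% counting interval 5.02 to 78.4). IAA12 again was higher, by 2.37 (SE 0.11, adjusted p = 6.25e-07). AT4G03923 had 0 against 1490 counts, at least 495-fold lower, MRD1 had 1 against 5720 and AT1G53887 had 0 against 272, at least 90.3-fold lower. AT3G41979, a ribosomal RNA locus that overlaps AT3G06355, was listed as lower too, though ribosomal reads were removed before counting. With the replicate block 8 loci passed, 5 higher and 3 lower, 7 of them among the 52. The count was 16 without Col-0 dex 3, 18 without GR-bdl dex 3, 21 without Col-0 dex 2 and 22 without GR-bdl dex 2.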

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

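The patterns weighed here were seen before any test of them was chosen. For the tests of a response shared with Col-0 and of organ boundary and floral genes the bounds were also set after their values were seen, and for the others before. With a preset correlation the test of the difference of responses to dex called 11 gene lists. Of 100 splits within the genotypes, the real one among them, 13 gave as many lists. The median of the other splits was 5 lists, so chance was not excluded for this count. Median differences, GR-bdl minus Col-0, were −0.676 for Aux/IAA, −0.474 for GH3, −0.837 for SAUR, −0.438 for auxin transport, −0.497 for cytokinin, −0.225 for gibberellin and −0.645 for vascular genes. They were 0.508 for organ boundary, 0.27 for circadian clock and 0.357 for wound, touch and jasmonate genes. MP-dependent genes had a median of −0.078 and a mean of −0.265. With 1 sample left out the organ boundary median was 0.318 (Col-0 dex 2) or 0.107 (Col-0 mock 2), and the clock median 0.117 (Col-0 dex 1) or 0.176 (Col-0 mock 2 and GR-bdl mock 2 alike). The wounding median rose to between 0.554 and 0.922 without Col-0 dex 2, dex 3, mock 1 or mock 3 or GR-bdl dex 3, mock 2 or mock 3. The gibberellin median was −0.114 (Col-0 dex 1), −1.18 (GR-bdl dex 2) or −0.126 (GR-bdl dex 3). The MP-dependent median ran from −0.359 (Col-0 mock 2) to 0.073 (GR-bdl mock 2), and Col-0 dex 1, dex 2 and mock 3 and GR-bdl dex 2, dex 3 and mock 3 also moved it by over 1.5 times. The SAUR median was −0.503 without Col-0 dex 1 and −0.552 without GR-bdl mock 2, and the vascular median −0.386 without Col-0 dex 2. A score of the vascular markers was also used as a covariate for GR-bdl dex against mock. The median of cytokinin genes then went from −0.431 to −0.128 (median SE 0.258 and 0.407), with a fry adjusted p = 0.342. That of MP-dependent genes went from −0.288 to −0.418 (median SE 0.227 and 0.326), with a fry adjusted p = 0.066. The score did not overlap between GR-bdl mock and GR-bdl dex. This covariate therefore cannot decide about vascular tissue, and less of it is not excluded for either list. With an estimated correlation the difference held for Aux/IAA, GH3 and auxin transport. Leaving out 1 sample ended the call for MP-dependent genes (GR-bdl dex 4), organ boundary genes (Col-0 dex 2), gibberellin genes (Col-0 mock 1 or GR-bdl dex 4), clock genes (Col-0 dex 1, Col-0 mock 1 or GR-bdl dex 4), vascular markers (Col-0 dex 2 or Col-0 mock 3) and wounding genes (Col-0 dex 1, mock 1 or mock 2, GR-bdl dex 2 or mock 2). Removing loci under a mean of 1 CPM ended it for gibberellin (adjusted p = 0.108), clock (0.0671) and vascular genes (0.0761).

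The fall of Aux/IAA, GH3 and SAUR genes in GR-bdl after dex was weighed first. A response to dex itself or to the order of harvest, which put mock before dex in both genotypes, would lower them in Col-0 too, but over their 51 members the median difference of responses was −0.69 (camera p = 0.000918 with an estimated correlation), and 48 were lower in GR-bdl against 26 in Col-0. Less vascular tissue in the GR-bdl dex samples could end the fall once a score of the vascular markers is a covariate. The medians were then −0.42 for Aux/IAA, −0.51 for GH3 and −0.77 for SAUR genes, with fry adjusted p = 0.0269, 0.00238 and 0.0902. The fall of SAUR genes thus kept its size without passing the threshold. However, the score did not overlap between GR-bdl mock (0.252 to 0.599) and GR-bdl dex (−0.367 to −0.045). It follows the treatment, so this covariate cannot decide whether less vascular tissue lay behind the fall. With that covariate 0 of the 10 loci passed over all genes. Errors grew, as for GH3.2 from −1.90 (SE 0.21) to −2.25 (SE 0.31), and for MAKR6 the change itself shrank from −2.55 (SE 0.31) to −1.88 (SE 0.41). For GH3.3 the change grew along with its error, from −1.46 (SE 0.21) to −2.01 (SE 0.28, edgeR adjusted p = 0.178). Why the calls were lost was not tested. Against Col-0 the medians were 0.56 in mock and −0.07 in dex for GH3, 0.17 and −0.41 for Aux/IAA, and 0.21 and −0.47 for SAUR genes. By its median the GH3 list thus started from a raised level and ended near that of Col-0. The GH3 genes that passed over all genes ended lower. Against Col-0 in dex GH3.2 had −1.13 and GH3.3 −0.48 (edgeR adjusted p = 0.0588 and 0.42). Repression by the activated bdl protein is the explanation the design offers and stays open, as no test here decides it.

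GH3 genes were higher in GR-bdl than in Col-0 without dex. More vascular tissue in the GR-bdl mock samples could raise them. With the vascular score as covariate the median was 0.50, against 0.56 without it. The score did not overlap between GR-bdl mock (0.252 to 0.599) and Col-0 mock (−0.324 to 0.126), so the covariate cannot part vascular tissue from genotype. One stray mock library is argued against, since leaving out each of the 6 gave medians of 0.47 to 0.636. What the line carries before induction, such as its insertion, some activity of the fusion without dex or a response to it, stays open, because a second line is not in the series.

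Organ boundary and floral identity genes were higher in GR-bdl after dex. Less vascular tissue, and so a larger share of young organs, is a candidate explanation, though tissue shares were not measured. With the vascular score as covariate the medians were 0.018 and 0.017, against 0.38 and 0.28 without it. The score did not overlap between GR-bdl mock and GR-bdl dex, so the covariate cannot decide this. Over the 33 members of both lists the median was 0.293 in GR-bdl and 0.022 in Col-0. The median difference of responses was 0.31 (camera p = 0.164 with an estimated correlation), so a response shared with Col-0 could not be excluded. A biological effect of bdl on these genes stays open and was not tested apart from less vascular tissue, since the vascular score also follows the treatment.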

How the results depend on the processing

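Quality weights and leaving out the 2 samples of lowest weight were chosen after the data were seen, and the other alternatives before. No count or named gene changed direction. The medians of 2 called lists did when 1 sample was left out, to 0.005 for gibberellin genes in GR-bdl (without GR-bdl mock 4) and to 0.019 and 0.073 for MP-dependent genes in the difference (without GR-bdl dex 2 or GR-bdl mock 2). RLE size factors, no filter, the stricter filter and limma-voom kept the counts of genes within 1.5 times, except that no filter gave 2 for the difference of responses, and Col-0 dex against mock had 0 in every setting. In GR-bdl dex against mock (10) the count was 65 with DESeq2, 4 with only the groups compared, 0 at adjusted p under 0.01, 3 against a fold of 1.2, 1706 with quality weights and 3336 without the 2 samples. For the difference of responses (0) it was 31 with DESeq2 and 2 with quality weights, and the compared groups alone were not run because all samples enter it. For GR-bdl against Col-0 in mock (19) it was 330 with DESeq2, 9 with the compared groups, 10 at adjusted p under 0.01, 12 against a fold of 1.2 and 135 with quality weights, and in dex (52) it was 390, 19, 13, 27 and 523, and 2874 without the 2 samples. The replicate block gave 0 in GR-bdl, 7 in mock and 8 in dex, ended the vascular call in mock and added those for mitotic genes (difference and mock), clock genes (mock) and organ boundary genes (dex), and it changed no other call of a list. Lists numbered 3 with an estimated correlation and 7 with fry in GR-bdl (12), 0 and 0 in Col-0 (5), and 3 and 4 for the difference (11), and 2 in Col-0 without the 2 samples. The stricter criterion itself explains the loss at adjusted p under 0.01 and against a fold of 1.2, and the fit of the compared groups has fewer samples. Col-0 mock 2, left out for the counts of 3336 and 2874, belongs to neither of those comparisons and enters them only through the shared fit. Elsewhere the cause was not tested.

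Leaving out 1 sample gave 0 to 5 genes in GR-bdl, 0 in Col-0, 0 to 1 for the difference, 9 to 17 in mock and 16 to 50 in dex, and 9 to 13, 1 to 11 and 8 to 14 lists in the first 3 comparisons. The log2 ratio of IAA12 (2.46) was 2.44 with raw totals, 2.46 with RLE and 2.42 to 2.49 without 1 sample, each at an exact permutation p = 0.0021645. Of the values of named genes, 38 of 38 stayed on their side of the threshold with DESeq2, RLE and no filter, 36 with limma-voom, 15 with the block and 126 of 228 when 1 sample was left out, all in the same direction. Averaged over genes the spread between samples was far above counting error, but abundant loci weigh most in that average. Depth limits folds of loci at 0 to 3 counts, and its part in the calls of other weakly expressed loci was not tested.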

Other observations

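The families of 3 of the fallen genes were looked at after those were seen, and without the fallen member none changed at an adjusted p under 0.05. Beside HAT2, the other 8 HD-ZIP II genes tested had a median log2 fold change of −0.11 in GR-bdl after dex, with 5 lower (fry adjusted p = 0.057). HB17 had −2.07 (SE 0.37, adjusted p = 0.105 over all genes). Beside NPY5, the other 4 NPY genes had a median of −0.25 (fry adjusted p = 0.057), with NPY4 at −0.43 (SE 0.16) and NPY1 at 0.08 (SE 0.11). Beside MAKR6, the other 4 MAKR genes tested had a median of 0.23 and 0 were lower (fry adjusted p = 0.057).

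Counting loci with at most 3 reads over the 6 samples of one genotype and at least 100 over those of the other gave 3 in GR-bdl and 6 in Col-0, a count made after the data were seen. The 3 were MRD1, AT4G03923 and AT1G53887. Of their nearest tested neighbours, 6 each, 0 passed in mock, with log2 differences of −0.61 to 0.40, while HEI10, which overlaps MRD1, had −1.91. Of the 6, AT4G36430, YLS9, AT1G13520, DMP1 and AT3G22620 had 64.6 to 96% of their reads in GR-bdl mock 3, and AT4G22505 had its 127 reads spread over the GR-bdl samples.

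The vascular score, the mean of the centred log2 levels of the 9 markers, was 0.252, 0.486 and 0.599 in the GR-bdl mock samples, −0.367, −0.256 and −0.045 in GR-bdl dex, 0.126, −0.002 and −0.324 in Col-0 mock and −0.382, 0.236 and −0.323 in Col-0 dex. Quality weights were lowest for Col-0 mock 2 (0.236) and GR-bdl dex 4 (0.336). Without both, list calls were lost in GR-bdl dex against mock for MP-dependent (adjusted p = 0.282), gibberellin (0.27), clock (0.143) and epidermal genes (0.11), and in Col-0 for auxin transport (0.115), wounding (0.732) and epidermal genes (0.0709). In the difference of responses they were lost for MP-dependent, clock and wounding genes (0.0957 each) and gibberellin genes (0.0575), in mock for auxin transport (0.0929) and wounding (0.191), and in dex for MP-dependent (0.668), auxin transport (0.0859) and cytokinin genes (0.515). The first 3 principal components held 26.8, 19 and 14.1% of the variance.

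The 6 samples of each direct comparison make 10 splits, too few for a share under 0.05. In GR-bdl dex against mock 1 of 10 splits gave as many genes (10, highest other 0) and 1 of 10 as many lists (12, highest other 10). In Col-0 dex against mock 10 of 10 gave as many genes (0, highest other 0), which a count of 0 fixes, and 4 of 10 as many lists (5, highest other 11). In GR-bdl against Col-0 in mock 1 of 10 gave as many genes (19, highest other 0) and 3 of 10 as many lists (4, highest other 7). In GR-bdl against Col-0 in dex 1 of 10 gave as many genes (52, highest other 0) and 4 of 10 as many lists (6, highest other 12). The real split parts all its pairs, as do 4 of 10 splits in each comparison, and among those the highest other count of genes was 0 in each, while that of lists was 6, 7, 4 and 12 in the order given. For the difference of responses 100 of 100 splits within the genotypes gave as many genes (0, highest other 3), which a count of 0 fixes and which tests nothing. Chance was not excluded for the lists, as 13 of 100 gave as many (11, highest other 14). With an estimated correlation 4 of 100 gave as many lists (3, highest other 8).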
